A study of Mus musculus with 70 samples.

How the data were processed

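The material was mouse hindlimb muscle, profiled by population-level sequencing of polyadenylated RNA in 70 libraries that form 28 groups and 6 experiments. In 5 experiments cells were released by enzymatic digestion, sorted by flow cytometry in 2 successive rounds, and 1000 cells per library were lysed for library construction, per the labels' protocols. The remaining experiment used whole tibialis anterior muscle, with 2 ng of purified RNA per library. The sorted populations were muscle mesenchymal stromal cells (MmSCs), muscle satellite cells (MuSCs), CD31+ cells, a gate that takes endothelial cells, and CD45+ cells, a gate that takes leukocytes. Groups and replicate numbers were taken from the sample labels. The labels number the libraries of a group as separate muscle samples and do not say which came from which animal, so the p-values measure the spread between these samples.

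The authors deposited 1 table of raw counts per gene, with 55011 gene symbols and 1 column per library, and no normalised values were used. Per the submitters' processing notes, the tools were STAR 2.7.3a, a spliced aligner, and featureCounts, which counts reads per gene, with the mm10 (GRCm38) build. The annotation version, the strand setting and the handling of reads that match several genes are not given in the sources used here, so genes with near-identical copies, overlapping genes and antisense genes may share reads. The number of unused columns of per-sample values was 0. Total counts per library ran from 2252373 to 8408842. By experiment the totals were 4774571 to 8408842 for cytokine injection, 2252373 to 7519352 for the sorted compartments, 4924282 to 7107525 for the Il6 reporter mice, 3176462 to 7178453 for whole muscle, 3507546 to 5960363 for mdx mice and 4802278 to 6812089 for Il1b-deficient mice. Counts of replicate libraries differed by more than counting noise in each group with replicates, with chi-square per degree of freedom from 4.228 to 55.97, so no library was treated as a copy of another. Gene coordinates were read from the GENCODE M21 annotation of GRCm38 by symbol.

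Each experiment was fitted on its own with edgeR 4.0.16 in R 4.3.3: genes passing filterByExpr with a minimum count of 10, TMM scaling factors, 1 mean per group, and the quasi-likelihood F-test with Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p under 0.05. The number of genes tested was 15965 for cytokine injection, 16374 for the compartments, 11975 for the reporter mice, 13346 for whole muscle, 13160 for mdx and 12102 for Il1b. The biological coefficient of variation was 18.2%, 22.4%, 29.6%, 21.6%, 16.5% and 12% in the same order. Scaling factors lay between 0.78 and 1.29. These fits gave 23 comparisons. The design, the lists and the alternatives were fixed before the data were examined, except where the text says otherwise. Values are CPM (counts scaled to library size, mean ± SD over libraries) and fitted log2 fold changes ± SE. The SE was back-calculated as the size of the log2 change divided by the square root of its quasi-likelihood F. It is unreliable for genes near 0 counts. Every adjusted p for a gene is from edgeR. For a gene with no count in 1 group, the fold is a lower bound against a floor of 3 counts per library and is written as at least N-fold. With 1 to 3 counts in a group, the ratio of counts corrected for library size is given with its 95% counting interval. These bounds and intervals cover counting error only.

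The genes named in the text follow a rule fixed beforehand. For the 2 h cytokine mix, injury in MmSCs, the reporter mice, anti-Cxcl5, both mdx comparisons and Il1b deficiency, these were up to 10 genes with the highest and 10 with the lowest fitted change among those called, with an average log2 CPM of at least 3 and no overlap between the libraries of both groups. For the other comparisons the rule took 5 and 5. Gene models without a name, mitochondrial transcripts and sex-linked genes used for sexing were left out, and some genes that the rule takes are not reported here. A fixed set of inflammatory and identity genes could be named anywhere: Il6, Cxcl5, Cxcl1, Cxcl2, Ccl2, Ccl7, Lif, Il1b, Il1r1, Osmr, Socs3, Nfkbia, Tnfaip3, Saa3, Thy1, Pdgfra, Ptprc, Pecam1 and Pax7. Up to 4 members of a list, those with the smallest p, could be named with it. Gm10800, an unnamed model whose share of counts is given for several experiments, and Ifi47 beside Olfr56 were added after their values were seen. In the text, the direction of a gene named by this rule holds in each library where 2 groups are compared. For the 3 interactions of cytokines and the MmSC response against the other compartments, overlap between libraries was not checked.

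The 26 lists, written from textbook knowledge, were chemokines and colony-stimulating factors, inflammatory cytokines, NF-kB targets and feedback, STAT3 and gp130 targets, interferon response, immediate-early and dissociation stress, collagens and matrix, matrix remodelling enzymes, cell cycle, ribosome biogenesis, glycolysis and hypoxia, oxidative phosphorylation and TCA cycle, adipogenic genes, regenerating myofibre, mature myofibre, and markers of MmSCs, MuSCs, endothelial cells, neutrophils, macrophages and monocytes, lymphocytes, haematopoietic cells in general, pericytes and smooth muscle, tenocytes, Schwann cells and erythroid cells. Each list was tested against all other genes with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Each was tested again with a correlation estimated from the data. Of 529 list tests, 193 passed 0.05 with the preset correlation and 67 of these passed in the same direction with an estimated correlation. The number of called members is given over all genes tested and adjusted over the list alone. Where 1 number is given, both adjustments gave that number. Signatures of called genes with a log2 change over 1 were tested in the same way in the experiments that share no library with them, in 58 tests.

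The reporter mice gave a Thy1.1+ and a Thy1.1- library under each replicate number. Deviations from the group means of same-numbered libraries correlated at r = 0.491, 0.54 and 0.742 across genes, and each library correlated best with its own number. The numbers were therefore taken as pairs, from the data and not from a statement in the labels, and the fit with replicate number as a block is given beside the unblocked one. Genes are not independent replicates in these correlations.

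All 7 comparisons of single cytokines and pairs, and those of the mix, share the same 2 PBS libraries. Overlaps between their calls are given with the largest overlap in 20 simulated draws of unchanged groups against those libraries, and with the overlap of independent lists. The labels do not say whether the PBS libraries were made together with the mix or with the single cytokines and pairs, so a difference between library sets is not separated from the effect of a cytokine in these comparisons. Part of any excess may come from the shared controls. Splitting them leaves 1 library on each side, whose spread is then assumed to be that of the other groups, and this split was added after seeing the data. The 4 h mix has 1 library, whose spread was assumed to be that of the other groups.

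The alternatives were DESeq2 size factors in edgeR, the DESeq2 1.42.0 Wald test, no low-count filter, a stricter filter of 50 counts, the replicate block, a fit on the compared groups only, limma voom with quality weights and a block on replicate number within day for the MmSC response against the other compartments, and each library left out in turn. List tests were repeated with fry, and overlaps and signatures at an adjusted p under 0.01. Il-17A libraries as the reference in place of PBS, and overlaps with the mix and the other groups set against different PBS libraries, were alternatives chosen after seeing the data. The median change of all genes tested was -0.224 on the log2 scale for injury in MmSCs, -0.119 for CD45+ cells and -0.102 for the MmSC response against the other compartments, so changes there are relative to a scaling that left the median gene below 0. With DESeq2 size factors in edgeR these medians were -0.308, -0.127 and -0.116, with -0.146 for CD31+ cells and -0.136 for MuSCs. In the DESeq2 test the median was -0.154 for mdx mice at 7 weeks and 0.123 for anti-Cxcl5.

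The edgeR steps were tested on simulated counts with 200 genes changed by known folds. Of genes changed 2-fold and 4-fold, 68% and 99% were recovered for the 2 h mix (14925 genes in that step), 62% and 93% for injury in MmSCs (15164 genes), 24% and 89% for Thy1.1 (11696 genes), 60% and 99% for anti-Cxcl5 (12989 genes), 89% and 100% for mdx at 7 weeks (12682 genes), and 91% and 100% for Il1b (11864 genes). The share of false calls was 6.7%, 2.5%, 7.4%, 7.6%, 5% and 9.9%, and 0 genes were called in the wrong direction. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15, with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 for the remaining steps.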

Results

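Transcript counts were measured in 70 libraries of mouse hindlimb muscle. The cytokine experiment held MmSCs, the fibroblast-like stromal cells of muscle, from uninjured mice injected intraperitoneally with PBS (n = 2) or with a mix of Il-1b, TNFa, oncostatin M (Osm) and Il-17A. Mix libraries were taken at 2 h (n = 2), 4 h (n = 1) and 8 h (n = 2). The sample labels give no time after injection for the PBS libraries, so that time is not separated from the effect of a cytokine. Further mice were taken at 2 h after each cytokine alone or with Osm paired with each of the other 3 (n = 2 each). The compartment experiment held CD31+ cells, CD45+ cells, MmSCs and MuSCs at homeostasis and 1 day after cardiotoxin, a snake venom toxin that kills myofibres (n = 3 each). Il6RD mice, in which cells that express Il6 are tagged with the surface marker Thy1.1, gave Thy1.1+ and Thy1.1- MmSCs 12 h after cardiotoxin (n = 3 each). Whole muscle was taken 7 days after cardiotoxin from mice given an antibody against Cxcl5, a neutrophil chemoattractant, or control IgG (n = 3 each). MmSCs of mdx mice, which lack dystrophin, were taken at 2.5 weeks (n = 3), 7 weeks (n = 3) and 12.5 weeks (n = 2). The labels differ on the age of this last group, with 12 weeks in the titles and 12.5 weeks in the descriptions of the cells, and the latter is used here. MmSCs of Il1b-deficient (n = 3) and wild-type (n = 2) littermates were taken 1 day after cardiotoxin. Library totals ran from 2252373 to 8408842 counts.

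The first comparison asked what the 4-cytokine mix does to MmSCs within 2 h. Transcripts of neutrophil-attracting chemokines rose from near the detection limit. Cxcl2 (chr5:90903871-90905938) was at least 687-fold higher, with 3359 counts against 0 in PBS, and Cxcl5 (chr5:90759360-90761624) rose from 0.322 ± 0.263 to 416 ± 57.6 CPM (SD, n = 2; log2 change 10.23 ± 1.26, adjusted p = 1.42e-06). Cxcl1 (chr5:90891241-90893115) rose by 7.68 ± 0.26 on the log2 scale (adjusted p = 2.35e-14), and the monocyte chemoattractant Ccl2 (chr11:82035571-82037453) by 4.77 ± 0.45 (adjusted p = 3.3e-08). Il6 (chr5:30013114-30019981), a cytokine that signals through gp130, went from 0.195 ± 0.0834 to 190 ± 87.1 CPM (n = 2), a ratio of 947 with a counting interval of 324 to 4600 (adjusted p = 5.19e-12). The acute-phase gene Saa3 (chr7:46711998-46715700) rose by 10.86 ± 0.83 and the interferon-inducible chemokine Cxcl10 by 9.62 ± 0.59. Acod1, which encodes the itaconate-producing enzyme of activated macrophages, was at least 146-fold higher, Tmem252 at least 135-fold and Olfr56 at least 57.3-fold. The annotated span of Olfr56 (chr11:48978889-49135387) holds the interferon-inducible gene Ifi47 (chr11:49076587-49096974) on the same strand, at 821 CPM in these libraries, so its counts may be shared. Csf2rb2, a cytokine receptor subunit, had a ratio of 952 with an interval of 263 to 7870. The feedback inhibitors Socs3, Nfkbia and Tnfaip3 rose by 4.8 ± 0.33, 4.56 ± 0.21 and 6.18 ± 0.36, and the receptor genes Osmr and Il1r1 by 3.23 ± 0.16 and 3.03 ± 0.21. Lif did not pass (0.9 ± 0.38, adjusted p = 0.0668), nor did the stromal markers Thy1 (-0.09, adjusted p = 0.697) and Pdgfra (0.3 ± 0.13, adjusted p = 0.0711).

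Transcripts that fell after 2 h of the mix included G0s2, an inhibitor of lipolysis (log2 change -6.69 ± 0.65, adjusted p = 8.46e-08), Pthlh, which encodes parathyroid hormone-related protein (-5.33 ± 0.55), and the p53 target Phlda3 (-5.19 ± 0.51). Lower too were the mesenchymal transcription factor gene Hic1 (-4.78 ± 0.48) and the cell cycle phosphatase gene Cdc25b (-4.6 ± 0.46). Prr33, Ccdc28b, Fam214a, Mrgprf and Apbb1 fell by between 4.16 and 5.42. In all, 3278 genes rose and 2871 fell of 15965 tested. Without each PBS or mix library in turn the number called stayed between 4857 and 5078.

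Several gene groups moved nearly as blocks at 2 h. All 25 measured NF-kB targets rose, over all genes and adjusted over the list alone (median log2 change 4.3, camera adjusted p = 9.35e-57, adjusted p = 5.19e-05 with an estimated correlation), led by Sod2, Birc3, Tnfaip6 and Nfkb2. All 30 interferon response genes rose under both adjustments (median 4.04, adjusted p = 1.37e-55, adjusted p = 0.000129 with an estimated correlation), and the guanylate-binding protein gene Gbp2 went from 59.1 to 3990 CPM. STAT3 and gp130 targets rose in 21 of 23, again 21 adjusted over the list alone (median 3.17, adjusted p = 1.68e-32, adjusted p = 5.55e-06 with an estimated correlation). Chemokines rose in 16 of 21, and 16 adjusted over the list alone (median 4.77, adjusted p = 3.28e-14, adjusted p = 0.000129 with an estimated correlation). All 22 ribosome biogenesis genes rose under both adjustments, among them Nop56, Gnl3 and Nop58 (median 2.73, adjusted p = 9.21e-46, adjusted p = 0.00187 with an estimated correlation). Of 19 matrix remodelling enzymes, 13 rose and 1 fell, with 14 and 1 adjusted over the list alone (adjusted p = 1.28e-06, adjusted p = 0.00386 with an estimated correlation); Plaur, Adamts1, Adamts4 and Has1 led. Immediate-early genes rose in 13 of 26 and fell in 1 (14 and 1 adjusted over the list alone; adjusted p = 0.000425, adjusted p = 0.237 with an estimated correlation). Glycolysis genes rose in 8 of 25 and fell in 1 (adjusted p = 0.00651, adjusted p = 0.165 with an estimated correlation). The collagen list did not pass (4 rose and 1 fell of 30, 3 and 1 adjusted over the list alone, adjusted p = 0.906). Neither did MmSC markers (4 and 1 of 17 under both adjustments, adjusted p = 0.683) or the cytokine list (5 and 1 of 14 under both, adjusted p = 0.0642). Adipogenic genes (1 rose and 2 fell of 13, adjusted p = 0.574), endothelial markers (1 and 1 of 8, adjusted p = 0.996) and macrophage markers (1 and 0 of 6, adjusted p = 0.996), with the same numbers adjusted over the list alone, did not pass either.

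At 4 h, in 1 library whose spread is assumed, Saa3 reached 12.3 ± 0.87 above PBS (adjusted p = 7.39e-10) and Cxcl5 10.38 ± 1.3 (adjusted p = 2.34e-06). Cxcl2 was at least 94.3-fold higher, Tmem252 at least 80.7-fold and Csf2rb, the common beta chain of several cytokine receptors, at least 73.4-fold. Rab30, a Golgi GTPase gene, was at least 68.9-fold lower, Cdc25b lower by a ratio of 115 (interval 31.8 to 956), and Pthlh, the growth arrest gene Gas1 and the pyruvate dehydrogenase kinase gene Pdk2 fell by 6.63 ± 0.82, 6.17 ± 0.76 and 5.63 ± 0.45. Collagens and matrix genes fell in 17 of 30 (19 adjusted over the list alone; adjusted p = 0.0025, adjusted p = 0.407 with an estimated correlation), and NF-kB targets rose in 23 of 25. In all, 3136 genes rose and 2683 fell.

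At 8 h, acute-phase transcripts were among those furthest above PBS, with Saa3 up by 12.79 ± 0.85 (adjusted p = 7.95e-10), Saa1 by 9.29 ± 0.67 and Saa2 by 8.66 ± 0.61. The interferon-inducible Ifi208 was at least 37.1-fold higher and Csf2rb2 had a ratio of 463 (interval 128 to 3830). Cxcl5 was 7.45 ± 1.32 above PBS (adjusted p = 0.000171) and Il6 stood at a ratio of 19.4 (interval 6.31 to 96.7). Ccl2 was below PBS (-3.05 ± 0.46, adjusted p = 3.23e-05), as were Lif (-2.58 ± 0.45) and Thy1 (-2.45 ± 0.17, adjusted p = 1.05e-09). The matrix protein gene Spon2 fell by 8.83 ± 0.7, Efhd1 by 6.89 ± 0.54, Stmn4 by 6.18 ± 0.7 and the proteoglycan gene Cspg4 by 5.98 ± 0.48, and Fam167a was lower by a ratio of 116 (interval 39.4 to 565). Collagens and matrix genes fell in 22 of 30 and rose in 3 (23 and 3 adjusted over the list alone; median -1.02, adjusted p = 1.54e-09, adjusted p = 0.104 with an estimated correlation). MmSC markers fell in 9 of 17 and rose in 2 (10 and 2 adjusted over the list alone; adjusted p = 0.000293, adjusted p = 0.0433 with an estimated correlation), led by Cd34, Cd248, Dpp4 and Ly6a. Glycolysis genes rose in 18 of 25 and fell in 2 (18 and 3 adjusted over the list alone; adjusted p = 2.85e-08, adjusted p = 0.0179 with an estimated correlation). STAT3 targets rose in 18 of 23 under both adjustments (adjusted p = 3.36e-27, adjusted p = 1.37e-05 with an estimated correlation). Pericyte and smooth muscle markers fell in 3 of 6 under both adjustments (adjusted p = 0.026, adjusted p = 0.136 with an estimated correlation) and Schwann cell markers in 2 of 6, or 3 adjusted over the list alone (adjusted p = 0.0467, adjusted p = 0.104 with an estimated correlation). In all, 2484 genes rose and 2052 fell. The 2 h and 8 h groups were each set against PBS and not against each other.

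**Figure D1:**
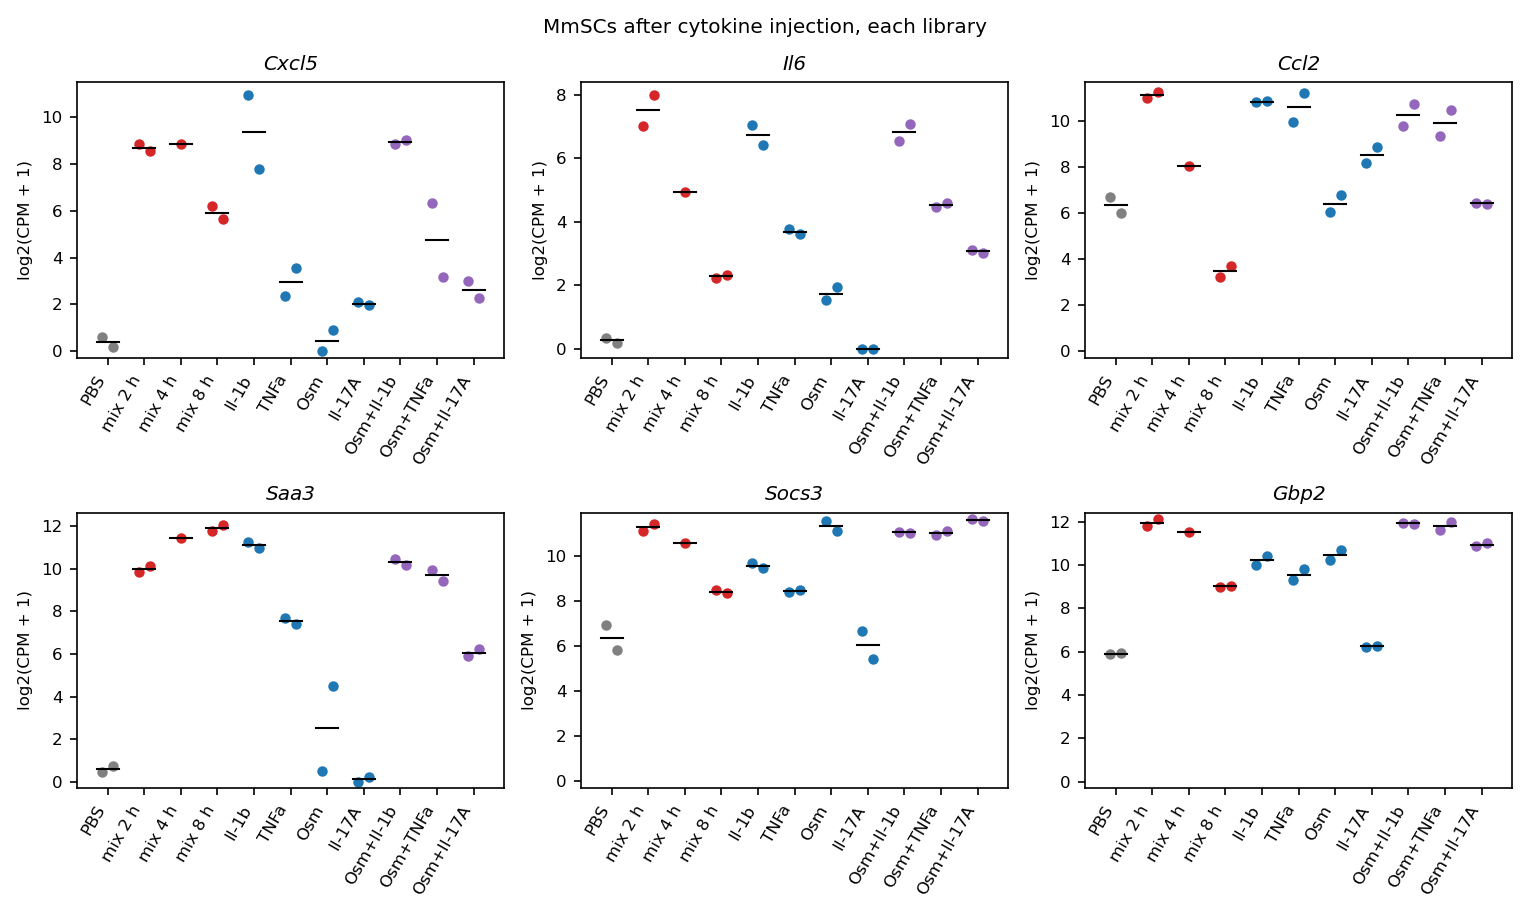
Each point is 1 MmSC library and each bar a group mean, with log2(CPM + 1) on the y axis and the injected cytokines on the x axis, for 6 genes. Cxcl5 means were 0.322 CPM in PBS and 416 CPM after 2 h of the mix, and Gbp2 means 59.1 and 3990 CPM.

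The single cytokines were injected to separate their parts in the 2 h response. Il-1b alone moved 5288 genes (3107 rose, 2181 fell). Cxcl2 was at least 491-fold higher, Saa3 rose by 12.01 ± 0.84 and Cxcl5 by 11.62 ± 1.26 (adjusted p = 4.4e-07), although its 2 libraries were far apart (1090 ± 1230 CPM, SD, n = 2). Il6 had a ratio of 542 (interval 185 to 2630), Cxcl1 rose by 7.37 ± 0.25, Ccl2 by 4.46 ± 0.44 and Socs3 by 3.09 ± 0.31, and Tmem252 and Acod1 were at least 45.3-fold and 27-fold higher. G0s2 fell by 5.05 ± 0.56 and Cdc25b by 4.31 ± 0.45. All 25 NF-kB targets rose under both adjustments (median 3.99, adjusted p = 3.78e-74), as did 17 of 21 chemokines, or 18 adjusted over the list alone (adjusted p = 1.48e-16). The cytokine list rose in 6 of 14 under both (adjusted p = 0.00536, adjusted p = 0.0271 with an estimated correlation).

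TNFa alone moved 2361 genes (1623 rose, 738 fell). Cxcl2 was at least 52.7-fold higher and Acod1 at least 10.5-fold, Saa3 rose by 8.43 ± 0.82 (adjusted p = 3.3e-07), the pentraxin gene Ptx3 by 6.39 ± 0.37 and Ccl2 by 4.35 ± 0.44, and Il6 had a ratio of 60.3 (interval 20.3 to 295). Cxcl5 did not pass (4.42 ± 1.67, adjusted p = 0.0844). The collagen-associated gene Cthrc1 and the metalloprotease gene Adam19 fell by 3.61 ± 0.89 and 2.91 ± 0.26. With Il-17A libraries in place of PBS, Cthrc1 was at -0.18 (adjusted p = 0.963) and Adam19 at -1.84 (adjusted p = 7.3e-05). NF-kB targets rose in 22 of 25, or 23 adjusted over the list alone (median 3.02, adjusted p = 4.97e-96). Interferon response genes rose in 17 of 30 and fell in 1 (20 and 1 adjusted over the list alone; adjusted p = 5.06e-19, adjusted p = 0.00622 with an estimated correlation). The number called was 993 with Il-17A libraries in place of PBS, 1182 without PBS replicate 2, 1213 without TNFa replicate 2, 1317 without PBS replicate 1 and 1579 without TNFa replicate 1.

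Osm alone moved 5482 genes (3014 rose, 2468 fell). Csf2rb was at least 128-fold higher, Ifi208 at least 39.8-fold and Olfr56 at least 18-fold, and the endothelial lipase gene Lipg rose by 7.43 ± 0.53. Socs3, the feedback inhibitor of gp130 signalling, rose by 4.87 ± 0.34 (adjusted p = 5.94e-10) and Ccl7 by 4.7 ± 0.38, whereas Ccl2 was at 0.05 ± 0.4 (adjusted p = 0.939) and Cxcl5 at 0.36 (adjusted p = 0.948). Il6 had a ratio of 11.9 (interval 3.72 to 60.5). Lif fell by 3.78 ± 0.51 and Tnfaip3 by 1.54 ± 0.39 (adjusted p = 0.00399). Saa3 was 4.34 ± 0.99 above PBS (adjusted p = 0.0017), but at -0.3 without Osm replicate 2. G0s2, Ccdc102a, Gas1, Slc9a3r2 and the prokineticin receptor gene Prokr1 fell by between 4.24 and 5.15. Interferon response genes rose in 29 of 30 under both adjustments (median 3.6, adjusted p = 1.51e-65, adjusted p = 0.000141 with an estimated correlation) and STAT3 targets in 19 of 23 under both (median 2.81, adjusted p = 1.28e-31). NF-kB targets rose in 16 of 25 and fell in 2 (17 and 2 adjusted over the list alone; adjusted p = 8.14e-07, adjusted p = 0.0771 with an estimated correlation).

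Il-17A alone moved 790 genes (453 rose, 337 fell). The monocyte chemoattractants Ccl7 and Ccl2 rose by 3.47 ± 0.36 (adjusted p = 3.94e-05) and 2.18 ± 0.41 (adjusted p = 0.00476), Cxcl1 by 2.99 ± 0.22 (adjusted p = 1.83e-07) and the phosphatase gene Dusp8 by 2.25 ± 0.5. Cyp27b1, which encodes the vitamin D-activating hydroxylase, had a ratio of 8.09 (interval 2.38 to 42.7). The matrix gene Tnc fell by 4.46 ± 1.15, Cthrc1 by 3.43 ± 0.9 and the sterol synthesis gene Fdft1 by 2.41 ± 0.34. TNFa against Il-17A libraries did not pass for Tnc (1.27, adjusted p = 0.646), Cthrc1 (-0.18, adjusted p = 0.963) or Fdft1 (0.42, adjusted p = 0.607). These falls are therefore not shown to be particular to Il-17A. Fdft1 is also among the genes shared by all 3 interactions below, for which a library batch stays open. Chemokines rose in 4 of 21 and fell in 1 (adjusted p = 1.38e-05, adjusted p = 0.0417 with an estimated correlation). NF-kB targets rose in 6 of 25, or 11 adjusted over the list alone (adjusted p = 1.73e-08, adjusted p = 0.0417 with an estimated correlation). These counts rest on few libraries: 100 genes were called without PBS replicate 1, 171 without PBS replicate 2, 334 without Il-17A replicate 1 and 142 without Il-17A replicate 2. Apart from fits with Il-17A libraries as the reference, differences between single cytokines were not tested directly.

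Osm was paired with each of the other 3 to ask how its action combines with theirs. Osm with Il-1b moved 6694 genes (3464 rose, 3230 fell). Cxcl2 was at least 322-fold and Acod1 at least 97.1-fold higher, Saa3 was up by 11.19 ± 0.83 and Cxcl5 by 10.46 ± 1.26, while G0s2 was lower by a ratio of 203 (interval 56.1 to 1680) and Phlda3 fell by 6.11 ± 0.58. Osm with TNFa moved 5911 genes (3268 rose, 2643 fell). Here Saa3 was up by 10.59 ± 0.83, Cxcl5 by 6.99 ± 1.35 (adjusted p = 0.000342), Cxcl2 was at least 56.3-fold and Acod1 at least 52.2-fold higher, and G0s2 was at least 80.1-fold lower. Osm with Il-17A moved 5681 genes (3102 rose, 2579 fell). Csf2rb was at least 68.4-fold and Ifi208 at least 26-fold higher, Saa3 rose by 6.93 ± 0.84 and the purinergic receptor gene P2ry1 fell by 4.69 ± 0.32. Interferon response genes rose in 30, 30 and 29 of 30 under the 3 pairs.

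Of the 3278 genes that rose with the mix at 2 h, 2422 (73.9%) also rose with Il-1b, 2253 (68.7%) with Osm, 1313 (40.1%) with TNFa and 277 (8.5%) with Il-17A. Independent lists of these sizes would share 638, 619, 333 and 93 genes, and simulated unchanged groups against the same PBS libraries shared at most 1. Such groups had 0.22 called genes on average, so that value does not show what shared controls add to lists of this length. The pairs shared 2781 (84.8%, Osm with Il-1b), 2608 (79.6%, Osm with TNFa) and 2358 (71.9%, Osm with Il-17A), against 711, 671 and 637 for independent lists. Of the 2871 genes that fell with the mix, 1583 (55.1%) also fell with Il-1b, 1423 (49.6%) with Osm, 510 (17.8%) with TNFa and 91 (3.2%) with Il-17A, against 392, 444, 133 and 61 for independent lists. Part of the excess may come from the 2 shared PBS libraries. In an alternative added after seeing the data, the mix was set against 1 PBS library and the other groups against the other, both ways round, with the spread of a lone library assumed. Higher genes shared with the mix were then 1768 and 1777 for Il-1b (396 and 392 for independent lists), 1691 and 1671 for Osm (400 and 390), 795 and 745 for TNFa (161 and 152) and 43 and 53 for Il-17A (9 and 14). Lower genes shared with Il-17A were 6 and 9, against 7 and 12 for independent lists.

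Departure of a pair from the sum of its single effects on the log2 scale was tested as an interaction. This sum is the product of the single folds, not a sum of transcript amounts. For Osm with Il-1b, 814 genes lay above the sum and 1701 below it. Of transcripts that each of these cytokines raised alone, those below the sum included Socs3 (-3.37 ± 0.42, adjusted p = 1.23e-05), Cxcl1 (-2.43 ± 0.28) and Osmr (-1.97 ± 0.21). With Il-17A libraries as the reference in place of PBS, Cxcl1 turned to 0.56 (adjusted p = 0.241), and 1230 genes were called in place of 2515. STAT3 targets lay below the sum in 17 of 23 (median -1.85, adjusted p = 3.09e-25, adjusted p = 2.7e-05 with an estimated correlation), and ribosome biogenesis genes in 20 of 22, with 1 above adjusted over the list alone (adjusted p = 5.09e-35, adjusted p = 0.0104 with an estimated correlation). For Osm with TNFa, 373 lay above and 571 below, with the interferon-inducible GTPase gene Ifi47 at -4.4 ± 0.36 (adjusted p = 3.32e-07). STAT3 targets lay below the sum in 12 of 23, or 15 adjusted over the list alone (adjusted p = 1.26e-19, adjusted p = 9.64e-05 with an estimated correlation). For Osm with Il-17A, 305 lay above and 104 below, with Ccl7 at -3.43 ± 0.47 (adjusted p = 0.000931) and Ccl2 at -2.21 ± 0.56 (adjusted p = 0.0393). PBS libraries had more genes detected at equal depth (18876 to 19008) than those of single cytokines and pairs (16721 to 17609), with mix libraries between 17100 and 18717. The unnamed gene model Gm10800 took 1.41% to 1.64% of counts in PBS and 0.869% to 1.41% in mix libraries, against 0.359% to 0.738% in those of single cytokines and pairs. These differences go with each comparison of a single cytokine or pair with PBS, and each interaction holds the PBS group. The Il-1b interaction called 1666 without PBS replicate 2 and 1672 without Osm with Il-1b replicate 2. The TNFa interaction called 214 with the Il-17A reference, 421 without TNFa replicate 2, 439 without PBS replicate 2, 520 without Osm replicate 2, 526 without Osm with TNFa replicate 2, 536 without PBS replicate 1, 586 without Osm with TNFa replicate 1 and 615 without Osm replicate 1. The Il-17A interaction called 109 without Osm with Il-17A replicate 2, 133 without Osm replicate 2, 184 without PBS replicate 1, 195 and 196 without Il-17A replicates 2 and 1, and 201 without PBS replicate 2.

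The compartment experiment asked how each population responds 1 day after cardiotoxin. In MmSCs, Cxcl5 rose from 0.322 ± 0.164 to 1550 ± 322 CPM (SD, n = 3; log2 change 12.05 ± 1.52, adjusted p = 7.53e-06). Ccl2 rose from 38.4 to 1930 CPM (5.65 ± 0.72), Ccl7 by 5.53 ± 0.54, Cxcl1 by 3.2 ± 0.41 and Il6 from 0.454 to 25.4 ± 6.9 CPM (5.84 ± 0.86, adjusted p = 1.31e-05), and Cxcl3 and Cxcl2 were at least 36.3-fold and 15.9-fold higher. The serpin gene Serpinb2 was at least 62.1-fold higher, and osteopontin (Spp1, chr5:104435118-104441050) had a ratio of 771 (interval 264 to 3740). Ms4a6d and Ccl9 were at least 16.7-fold and 9.72-fold higher, the Il-33 receptor gene Il1rl1 rose by 8.55 ± 1.09, and Saa3 rose by 7.9 ± 0.73 (adjusted p = 8.31e-08). The adipocyte and muscle carbonic anhydrase gene Car3 was lower by a ratio of 456 (interval 156 to 2220) and the myosin light chain gene Myl1 by a ratio of 332 (interval 59.1 to 13200), and the skeletal actin gene Acta1 fell by 7.21 ± 0.59. Ighm, an immunoglobulin heavy chain gene, fell by 6.65 ± 0.92. Mlxipl, Lrrn1, Clic5, Bcam and Ms4a8a were at least 3.17-fold to 4.93-fold lower. Thy1 fell by 1.19 ± 0.28 (adjusted p = 0.00163), while Pdgfra was at 0.2 (adjusted p = 0.812). In all, 2981 genes rose and 3871 fell of 16374 tested. Gm10800 took 0.678% to 0.851% of counts at day 0 and 0.206% to 0.347% at day 1, and genes detected at equal depth went from between 18017 and 18426 to between 16803 and 17281.

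Cell cycle genes rose in 28 of 30 in injured MmSCs under both adjustments (median 4.01, adjusted p = 1.13e-15, adjusted p = 0.135 with an estimated correlation). Ribosome biogenesis genes rose in 22 of 22 under both (median 2.41, adjusted p = 3.98e-42, adjusted p = 0.000162 with an estimated correlation), and oxidative phosphorylation genes rose in 20 of 25 and fell in 2 (adjusted p = 1.39e-10, adjusted p = 0.0379 with an estimated correlation). STAT3 targets rose in 14 and fell in 2 (adjusted p = 5.46e-06, adjusted p = 0.104 with an estimated correlation), and NF-kB targets rose in 16 and fell in 1, or 16 and 2 adjusted over the list alone (adjusted p = 0.000414, adjusted p = 0.219 with an estimated correlation). MmSC markers fell in 12 of 17 and rose in 1 (median -2.07, adjusted p = 4.49e-06, adjusted p = 0.0789 with an estimated correlation). Collagens and matrix genes fell in 17 and rose in 6, or 18 and 6 adjusted over the list alone (adjusted p = 0.0482, adjusted p = 0.619 with an estimated correlation). Mature myofibre transcripts, which belong to differentiated muscle fibres, fell in 15 of 16 in the same libraries (median -5.04, adjusted p = 2.5e-09, adjusted p = 0.0597 with an estimated correlation). Tenocyte markers fell in 5 without passing as a list (adjusted p = 0.558), and lymphocyte and general haematopoietic markers had 0 called members by edgeR.

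In MuSCs, Pax7, the satellite cell transcription factor gene, fell from 584 ± 70.6 to 232 ± 26.1 CPM (log2 change -1.33 ± 0.31, adjusted p = 0.00254). MuSC markers fell in 10, or 11 with 1 higher adjusted over the list alone (median -1.21, adjusted p = 2.9e-06, adjusted p = 0.00659 with an estimated correlation). Cell cycle genes rose in 28 of 30 under both adjustments (median 3.7, adjusted p = 2.26e-13, adjusted p = 0.237 with an estimated correlation). Ccl2 rose by 7.78 ± 0.99, Cxcl5 was at least 182-fold higher (135 ± 179 CPM), and the matrix metalloprotease gene Mmp3, the pentraxin gene Nptx1 and Cxcl3 were at least 99.2-fold, 97.3-fold and 39.2-fold higher. The heparanase gene Hpse fell by 4.91 ± 0.87. The injured MuSC libraries also held transcripts of stromal cells: Pdgfra reached 25.4 ± 24.7 CPM, a ratio of 161 (interval 44.4 to 1340), and Dcn, chosen after its values were seen, 213 ± 177 CPM, both unequal between libraries. The regenerating myofibre list, which holds Myod1, rose in 4 and fell in 2 (4 and 3 adjusted over the list alone). In all, 3501 genes rose and 2856 fell, and the Gm10800 share went from between 1.71% and 2.18% to between 0.572% and 0.703%.

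In CD45+ cells, Cxcl3 had a ratio of 2110 (interval 378 to 83400) and Cxcl1 of 278 (interval 76.6 to 2300). Arginase 1 (Arg1), which marks alternatively activated myeloid cells, rose by 7.76 ± 0.34 (adjusted p = 1.2e-12), the protease inhibitor gene Timp1 by 7.58 ± 0.74 and Spp1 by 7.36 ± 0.85. Il1b rose from 866 ± 564 to 4960 ± 1460 CPM (2.52 ± 0.82, adjusted p = 0.0218). The phospholipase gene Pla2g2d was lower by a ratio of 1580 (interval 282 to 62300) and Mamdc2 by 507 (interval 90.6 to 20100). The makeup of the gate differed as well. Neutrophil markers rose in 10 of 12 under both adjustments, led by Clec4d, Cxcr2, Il1r2 and S100a8 (adjusted p = 0.000787, adjusted p = 0.273 with an estimated correlation). Lymphocyte markers fell in 14 of 15 under both, with the B cell gene Cd79a going from 535 to 4.01 CPM (median -4.98, or -4.47 with genes at 0 at their bound; adjusted p = 3.99e-07, adjusted p = 0.0519 with an estimated correlation). Macrophage and monocyte markers rose in 7 and fell in 4, or 8 and 4 adjusted over the list alone (adjusted p = 0.044, adjusted p = 0.578 with an estimated correlation), and erythroid transcripts fell in 4 without passing as a list (adjusted p = 0.313). Beside these, glycolysis genes rose in 18, or 20 adjusted over the list alone (adjusted p = 3.76e-18, adjusted p = 0.00158 with an estimated correlation), and cell cycle genes fell in 21, or 22 adjusted over the list alone (adjusted p = 9.43e-05, adjusted p = 0.438 with an estimated correlation). In all, 2611 genes rose and 3054 fell, and the Gm10800 share went from between 2.399% and 3.18% to between 1.72% and 1.74%.

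In CD31+ cells, Ccl2 was at least 65-fold and the metallothionein gene Mt2 at least 19.7-fold higher. AA467197 rose by 8.41 ± 0.45 (adjusted p = 6.72e-11), Sh2d5 by 8.06 ± 0.65 and Il6 by 4.03 ± 0.83 (adjusted p = 0.00107), and the decoy receptor gene Il1r2 was at least 7.27-fold higher. Among transcripts that fell, Fndc1 was at -4.48 ± 0.57, Comp at -3.4 ± 0.99, Adamts15 at -3.35 ± 0.85 and Cpxm2 at -3.21 ± 0.78, and Epdr1 was lower by a ratio of 18.5 (interval 2.73 to 789). These 5 transcripts stood at 0.968 to 41.8 CPM in uninjured CD31+ cells and at 35.8 to 1460 CPM in uninjured MmSCs, so transcripts abundant in another cell type fell in these libraries. Tenocyte markers fell in 2 without passing as a list (median -1.6, or 0 with genes at 0 at their bound; adjusted p = 0.535). Interferon response genes fell in 26 under both adjustments (median -1.16, adjusted p = 1.08e-12, adjusted p = 0.0345 with an estimated correlation), and ribosome biogenesis genes rose in 22 of 22 under both (adjusted p = 1.43e-44). Endothelial markers fell in 5, or 7 adjusted over the list alone (adjusted p = 0.00443, adjusted p = 0.307 with an estimated correlation), and general haematopoietic markers rose in 8 under both without passing as a list (adjusted p = 0.058). Il1b had a ratio of 115 (interval 31.7 to 956), but its fitted change was -0.8 without injured CD31+ replicate 1, and the myeloid gene Lyz2, chosen after its values were seen, went from 0.512 ± 0.196 to 37.5 ± 63.3 CPM. In all, 2324 genes rose and 1531 fell (60.3% higher), against 1941 and 2073 (48.4% higher) with DESeq2 size factors. The Gm10800 share went from between 4.999% and 7.79% to between 2.515% and 2.9%.

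Whether the injury response of MmSCs differed from the mean response of the other 3 compartments was tested directly. Relative to that mean, cell cycle genes lay higher in MmSCs in 25 of 30, or 28 adjusted over the list alone (median 3.4, adjusted p = 1.11e-28, adjusted p = 0.0517 with an estimated correlation). Ribosome biogenesis genes did so in 17 of 22, or 18 adjusted over the list alone (adjusted p = 0.00602 with an estimated correlation). The mean holds CD45+ cells, where cell cycle genes fell in 21, and MuSCs, where they rose in 28 of 30, and a difference from MuSCs alone was not tested. The cycle gene Cdca7l lay 6.93 ± 0.68 above the mean of the others (adjusted p = 8.36e-07), Lmcd1 5.84 ± 0.55 above, and Il1r1 1.57 ± 0.34 above (adjusted p = 0.00252). The placental growth factor gene Pgf lay below it (-6.27 ± 0.52, adjusted p = 7.74e-08), as did the phospholipase gene Pla1a (-5.8 ± 0.62). Cdca7l, Pgf and Pla1a have at least 1 group with 0 to 3 counts in all, so their fitted differences depend on the prior count. In all, 1034 genes lay above and 1364 below. The number called was 1571 without injured MmSC replicate 1.

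**Figure D2:**
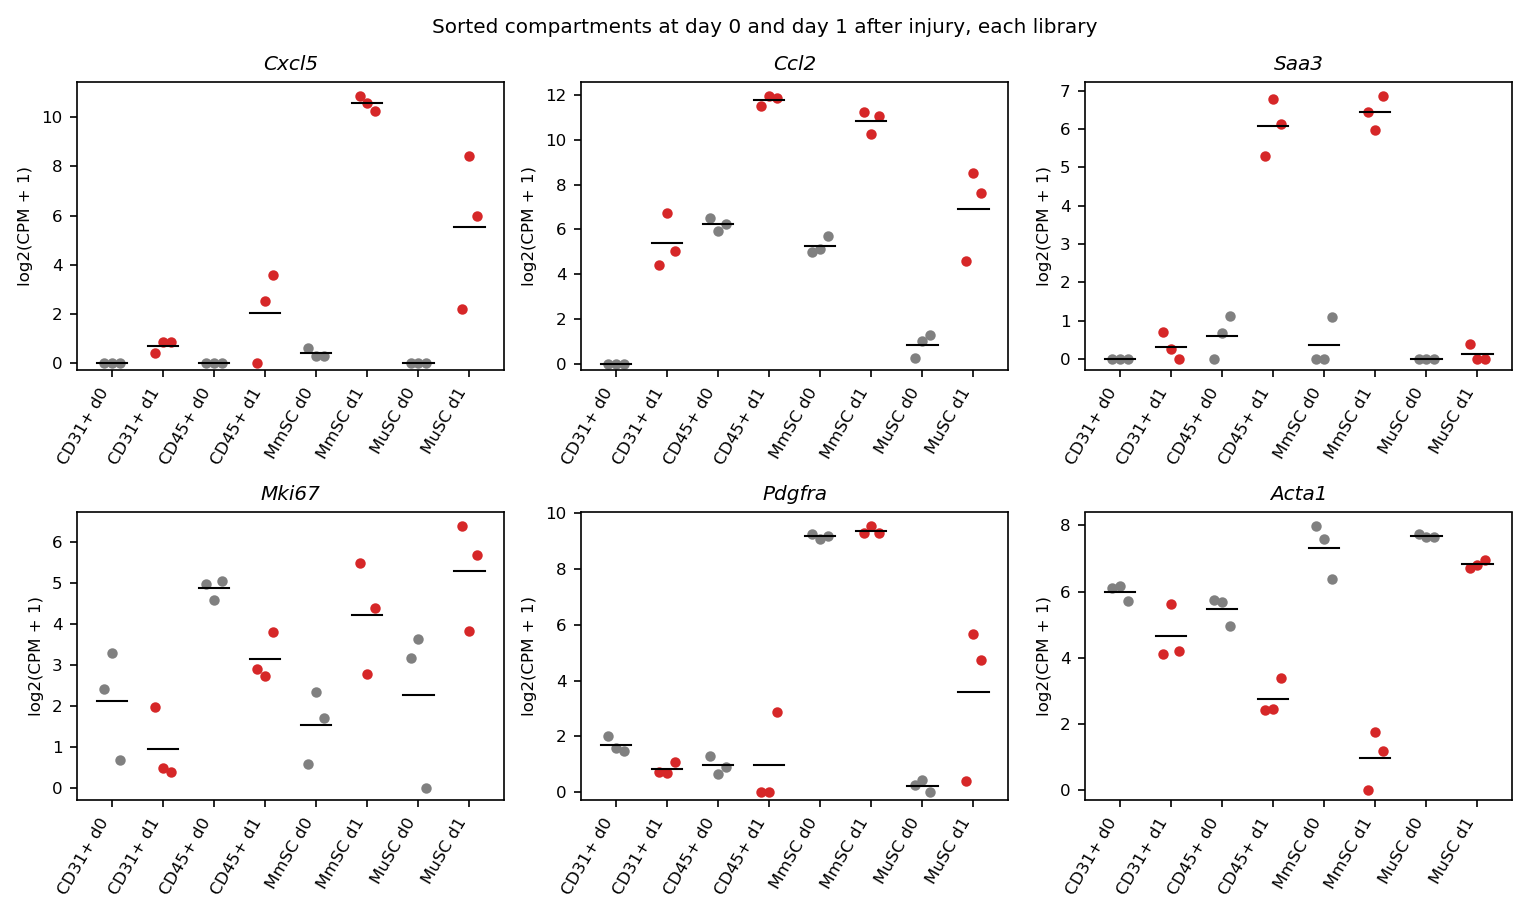
Each point is 1 library and each bar a group mean, with log2(CPM + 1) on the y axis and compartment and day after cardiotoxin on the x axis, for 6 genes. In MmSCs the Cxcl5 means were 0.322 CPM at day 0 and 1550 CPM at day 1.

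Signatures were carried across experiments that share no library. Of 1682 genes that defined injury in MmSCs and were measured in the cytokine experiment, 904 rose and 44 fell with Il-1b (median 0.84, adjusted p = 0.0124 with an estimated correlation). With Osm 915 rose and 57 fell (median 0.87, adjusted p = 0.0113 with an estimated correlation), and 873 rose and 85 fell with the mix at 2 h (median 0.79, camera adjusted p = 6.66e-22, adjusted p = 0.0167 with an estimated correlation). With TNFa 496 rose and 33 fell (median 0.37, adjusted p = 1.78e-13, adjusted p = 0.0531 with an estimated correlation), and with Il-17A 160 rose and 25 fell (median 0.21, adjusted p = 1.02e-06, adjusted p = 0.186 with an estimated correlation). In the other direction, the Il-1b signature rose in 857 and fell in 147 of 1611 genes after injury (median 0.8, adjusted p = 0.000315 with an estimated correlation). In whole muscle after anti-Cxcl5, no signature passed (adjusted p from 0.398 to 0.812).

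Thy1.1+ and Thy1.1- MmSCs were compared to ask whether Il6-tagged cells carry more inflammatory transcripts. In Thy1.1+ cells Il6 was at 139 ± 131 against 44.3 ± 22.6 CPM (SD, n = 3), Cxcl5 at 6940 ± 1030 against 3270 ± 1410 CPM and Ccl2 at 5240 ± 267 against 3000 ± 123 CPM. Without the pairing edgeR called 0 of 11975 genes, with 1258 at an unadjusted p under 0.05, a smallest adjusted p of 0.109 and 120 called by DESeq2. Il6 was at 1.65 ± 0.67 (adjusted p = 0.448), Cxcl5 at 1.09 ± 0.35 (adjusted p = 0.354) and Ccl2 at 0.81 ± 0.17 (adjusted p = 0.253). With replicate number as a block 1286 genes passed (590 higher, 696 lower). In that fit Il6 was higher by 1.41 ± 0.2 (adjusted p = 0.000543). The cells were sorted on a tag of Il6 expression, so Il6 checks the sort only. Cxcl5 was higher by 1.18 ± 0.18 (adjusted p = 0.00124) and Cxcl2 by 1.86 ± 0.22. Cxcl1 was higher by 0.75 ± 0.11, Ccl2 by 0.8 ± 0.09 (adjusted p = 0.000116), Ccl7 by 0.53 ± 0.09 and the matrix gene Tnc by 1.58 ± 0.13. Lower in the blocked fit were Cd248 (-2.37 ± 0.15, adjusted p = 2.75e-06; 36.9 ± 11.1 against 189 ± 19 CPM), Dpp4 (-2.27 ± 0.19) and Pi16 (-2.01 ± 0.16), with Gbp2 at -1.73 ± 0.15 and Fn1 at -1.12 ± 0.11. Thy1 itself did not pass (0.59, adjusted p = 0.0515). Tnc, Cd248, Dpp4, Pi16, Gbp2 and Fn1 were chosen after their values were seen. In each of the 3 pairs the Thy1.1- library had the larger share of Gm10800 (0.614%, 0.691% and 1.356% of counts, against 0.491%, 0.351% and 0.767%) and more genes detected at equal depth (18137, 17817 and 19270, against 17436, 16998 and 17800), so both differences go with the blocked calls. Unblocked, 2 genes were called without Thy1.1+ replicate 3.

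Without the block, chemokines had 0 called of 17 and 6 higher adjusted over the list alone (median 0.59, adjusted p = 1.4e-06). Medians were positive for NF-kB targets (0.43, adjusted p = 3.47e-06), the cytokine list (1.02, adjusted p = 0.0037) and ribosome biogenesis (0.39, adjusted p = 7.15e-08). All 4 lists had adjusted p = 0.322 with an estimated correlation. MmSC markers had 6 of 17 lower adjusted over the list alone (median -0.29, adjusted p = 9.8e-07, adjusted p = 0.323 with an estimated correlation). With the block, 7 of 17 chemokines, 4 of 11 cytokines, 6 of 25 NF-kB targets and 13 of 22 ribosome biogenesis genes rose, against 10, 6, 15 and 14 called adjusted over the list alone. In that fit 8 of 17 MmSC markers fell with 1 higher, 12 of 30 collagens and matrix genes fell with 2 higher, and 8 of 28 interferon response genes fell, against 11, 18 and 9 called adjusted over the list alone. All 7 lists had adjusted p = 0.41 with an estimated correlation. Some genes taken here as markers of other cell types fell in the blocked fit too. These were the tenocyte gene Fmod (-2.45, adjusted p = 0.000112), the endothelial gene Tek (-2.34, adjusted p = 2.37e-05) and Acta1 (-1.43, adjusted p = 0.0225), among others. Tnmd (-0.75, adjusted p = 0.256), Thbs4 (0.36, adjusted p = 0.153), Flt1 (0.07, adjusted p = 0.939) and Atp2a1 (-1.24, adjusted p = 0.102) did not pass. In Thy1.1- libraries Tek stood at 37.8 ± 16.4 CPM and Flt1 at 4.03 ± 0.258 CPM, and which cells held these transcripts was not tested. These markers were chosen after their values were seen.

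**Figure D3:**
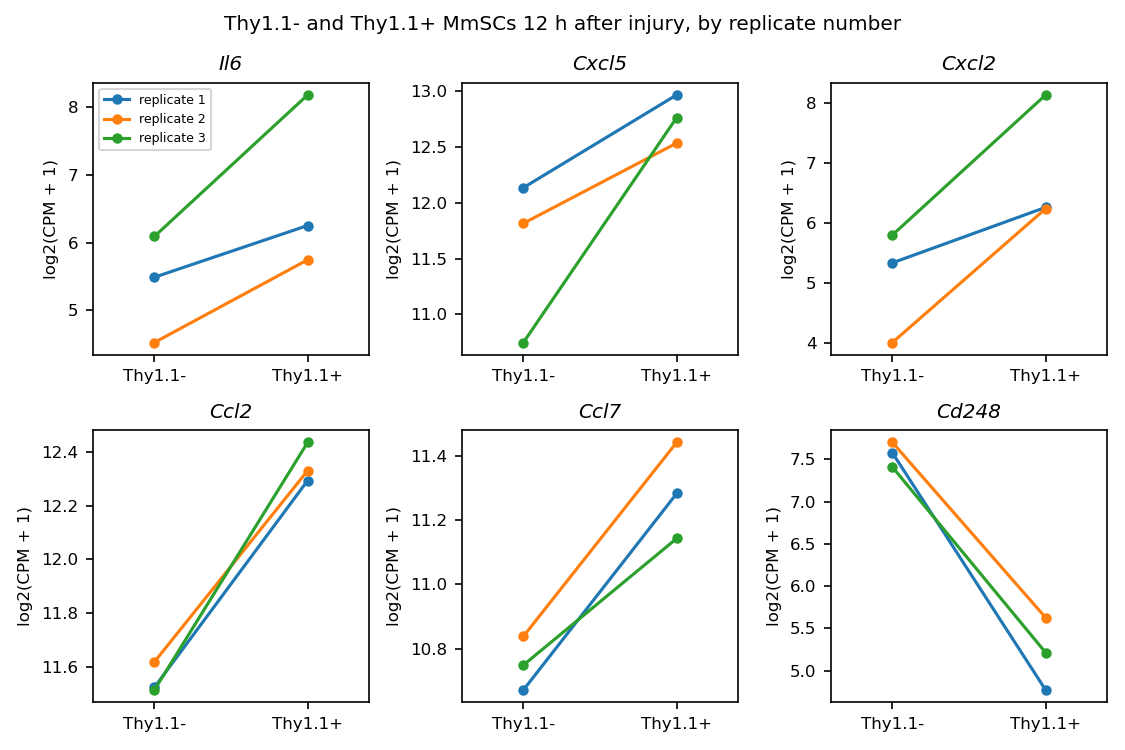
Each line joins the Thy1.1- and Thy1.1+ libraries that share a replicate number, with log2(CPM + 1) on the y axis, for 6 genes. The Ccl2 means were 3000 and 5240 CPM and the Cd248 means 189 and 36.9 CPM.

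Whole muscle was compared 7 days after cardiotoxin to see what blocking Cxcl5 changes. Macrophage markers stood higher as a group after anti-Cxcl5, with C1qc, a complement component gene, at 109 ± 22.6 against 48.7 ± 21.5 CPM (SD, n = 3). The libraries also stood apart in genes detected at equal depth (19237 to 19903 after anti-Cxcl5, 17862 to 18310 after IgG) and in the summed counts of olfactory receptor genes (84.4 to 180 against 40 to 43.4 CPM), which muscle hardly transcribes. Of 20 macrophage markers 0 were called over all genes and 10 were higher adjusted over the list alone, led by C1qc, Ctss, Trem2 and Gpnmb (median 0.42, adjusted p = 5.92e-12, adjusted p = 0.466 with an estimated correlation). General haematopoietic markers had 7 of 13 higher adjusted over the list alone (median 0.76, adjusted p = 5.8e-10, adjusted p = 0.491 with an estimated correlation), with the pan-leukocyte gene Ptprc at 0.82 ± 0.26 (adjusted p = 0.821). Neutrophil markers had 4 measured members (median 0.7, adjusted p = 0.0444, adjusted p = 0.491 with an estimated correlation) and lymphocyte markers 9 (median 0.4, adjusted p = 0.228). Endothelial markers (0 called of 16, 1 lower adjusted over the list alone; median -0.27, adjusted p = 0.000191) and oxidative phosphorylation genes (median -0.18, adjusted p = 9.35e-07) stood lower, each with adjusted p = 0.522 with an estimated correlation, as did mature myofibre genes (median -0.13, adjusted p = 0.00505, adjusted p = 0.584 with an estimated correlation). Regenerating myofibre genes were at 0.13 (adjusted p = 0.0744), and Ccl2 was at -0.03 (adjusted p = 0.995). Cxcl5 did not pass the count filter.

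Of 13346 genes, 4 rose and 0 fell by edgeR, with 770 at an unadjusted p under 0.05 and 7 called by DESeq2. The 4 are unnamed gene models, given here after their values were seen: Gm10800 (chr2:98666547-98667301, 3.16 ± 0.34, adjusted p = 0.0233), Gm10801 (chr2:98662237-98664083, 2.93 ± 0.35, adjusted p = 0.0249), Gm21738 (chr14:19415857-19418930, 2.76 ± 0.33, adjusted p = 0.0249) and Gm10717 (chr9:3025417-3033289, 3.34 ± 0.45, adjusted p = 0.0498). Such models may share reads. Gm10800 stood at 730, 2140 and 1440 CPM after anti-Cxcl5 and at 171, 165 and 119 CPM after IgG. The number called was 0 without IgG replicate 1, 2 or 3 or anti-Cxcl5 replicate 3.

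MmSCs of mdx mice at 2.5, 7 and 12.5 weeks of age were compared to cover stages of the disease. No wild-type MmSCs are labelled with these ages, so disease stage cannot be told apart from growth with age. Between 2.5 and 7 weeks Spp1 rose from 0.327 ± 0.567 to 174 ± 94.3 CPM (SD, n = 3; log2 change 8.93 ± 0.56, adjusted p = 3.75e-08). The collagenase gene Mmp13 rose by 7.85 ± 0.54, the tenascin gene Tnn by 6.98 ± 0.4, the adhesion gene Nfasc by 6.11 ± 0.35 and the chemokine gene Cxcl14 by 5.84 ± 0.34. Gpr176, Hp, Sema7a and Slpi rose by 5.96, 5.76, 5.76 and 5.47, and the potassium channel gene Kcnj15 had a ratio of 105 (interval 35.6 to 511). Cxcl5 went from 133 ± 92.9 to 1850 ± 547 CPM (3.8 ± 0.42, adjusted p = 6.79e-06), Lif rose by 2.58 ± 0.35, Ccl7 by 1.49 ± 0.14 and Ccl2 by 0.95 ± 0.16, and Il6 did not pass (0.44 ± 0.2, adjusted p = 0.0835). The fetal growth factor gene Igf2 (chr7:142650766-142666816) fell from 104 ± 18.4 to 0.735 ± 0.581 CPM (-7.06 ± 0.31, adjusted p = 2.37e-09), Mrgprg was lower by a ratio of 378 (interval 67.4 to 15000), and Clic5, Akr1c18, Engase, Spock3, Zbtb16, Nrk, Dcaf12l1 and Epha7 fell by between 3.5 and 4.37. Chemokines rose in 15 and fell in 2 (adjusted p = 2.06e-10, adjusted p = 0.312 with an estimated correlation). Cell cycle genes rose in 26 of 30 (median 2.34, adjusted p = 5.79e-10, adjusted p = 0.371 with an estimated correlation). Collagens and matrix genes rose in 14 and fell in 5 (adjusted p = 0.00395, adjusted p = 0.404 with an estimated correlation). Tenocyte markers rose in 6 in the same libraries (median 1.71, adjusted p = 0.000204, adjusted p = 0.352 with an estimated correlation). In all, 2883 genes rose and 2981 fell of 13160 tested. Gm10800 took 0.679% to 0.784% of counts at 2.5 weeks and 0.329% to 0.383% at 7 weeks, and genes detected at equal depth went from between 19100 and 20078 to between 17758 and 18246.

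Between 7 and 12.5 weeks the complement gene C7 (chr15:4988762-5063740) rose from 24.9 ± 14.2 (n = 3) to 249 ± 81.7 CPM (n = 2; 3.33 ± 0.35, adjusted p = 0.000287), Clic5 rose by 3.47 ± 0.75, and the cartilage matrix gene Chad by 2.81. Galnt15, Gpr165, Acsbg1, the angiotensinogen gene Agt, Fam180a, Inmt and Ppl rose by between 2.11 and 2.59. The mitotic genes Birc5 and Cdc20 fell by 2.81 and 2.45, the imprinted RNA gene H19 by 2.48, Serpinb2 by 3.92 ± 0.98 and the osteoprotegerin gene Tnfrsf11b by 2.59. Cell cycle genes fell in 13 of 30, or 24 adjusted over the list alone (median -1.75, adjusted p = 7.08e-22, adjusted p = 0.271 with an estimated correlation). MmSC markers rose in 7, or 11 adjusted over the list alone (median 0.52, adjusted p = 2.48e-10, adjusted p = 0.271 with an estimated correlation). Tenocyte markers rose in 3 (adjusted p = 0.000831, adjusted p = 0.438 with an estimated correlation). Ccl2 fell by 0.67 ± 0.18 (adjusted p = 0.0388), and Cxcl5, at 650 ± 3.93 CPM, did not pass (-1.51 ± 0.44, adjusted p = 0.0565). In all, 463 genes rose and 314 fell, but the number called was 137 and 140 without 12.5-week replicates 1 and 2, and 253, 380 and 481 without 7-week replicates 1, 2 and 3. A fit on these groups alone called 2027.

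**Figure D4:**
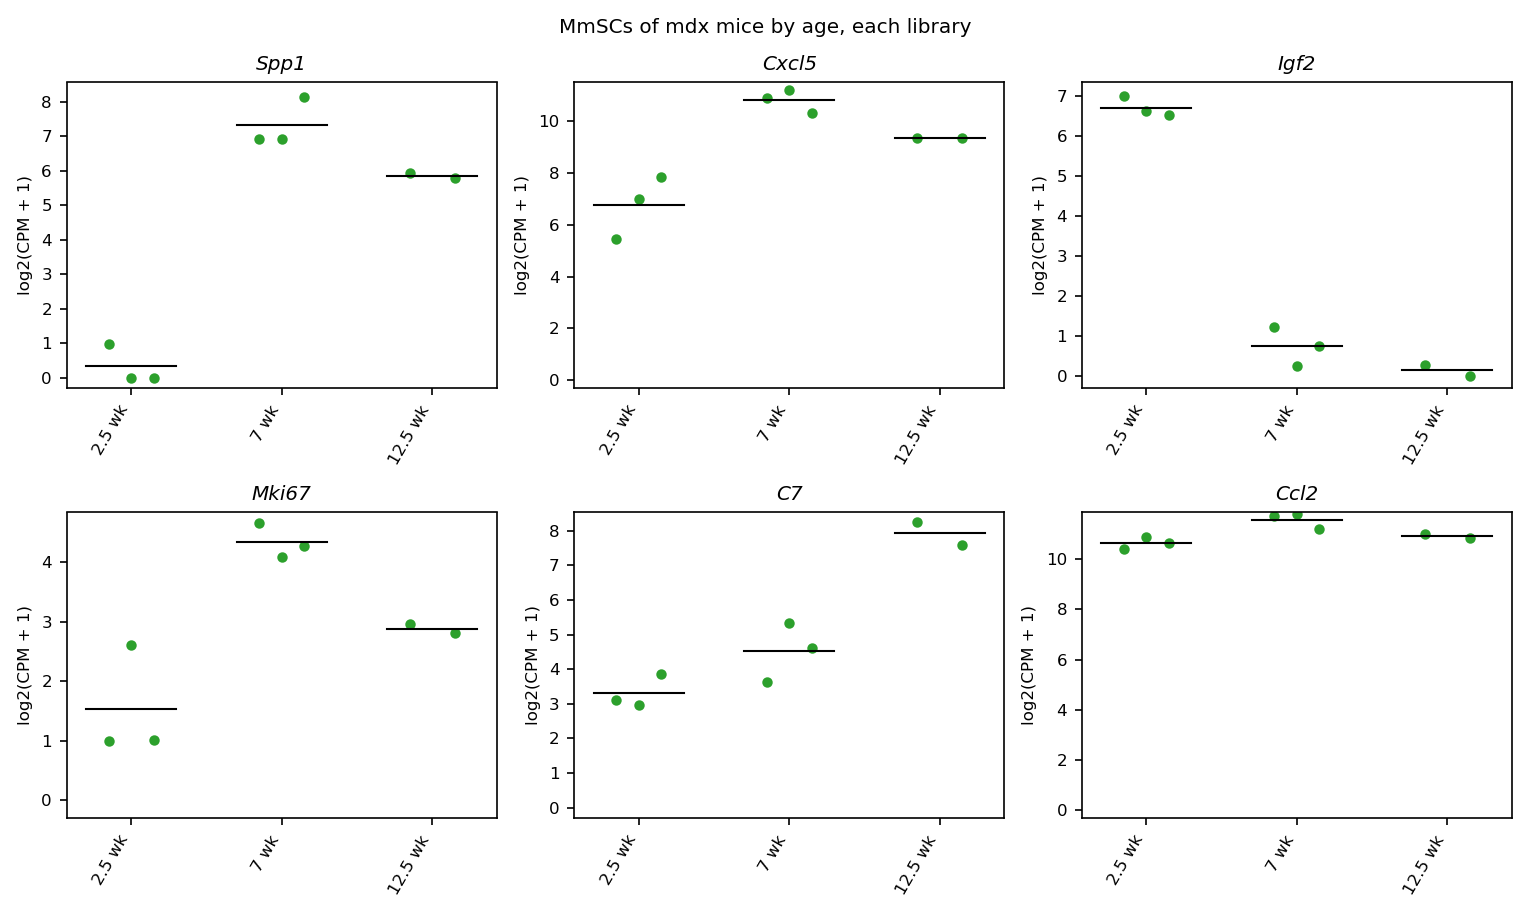
Each point is 1 library of mdx MmSCs and each bar a group mean, with log2(CPM + 1) on the y axis and age in weeks on the x axis, for 6 genes. Igf2 means were 104 CPM at 2.5 weeks and 0.735 CPM at 7 weeks.

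The signature of injury in MmSCs had 803 higher and 93 lower of 1620 genes at 7 weeks (median 0.54, adjusted p = 1.67e-16, adjusted p = 0.0992 with an estimated correlation). It had 32 higher and 132 lower at 12.5 weeks against 7 weeks (median -0.21, adjusted p = 1.75e-08, adjusted p = 0.231 with an estimated correlation). In Thy1.1+ cells it had 0 called genes of 1557 without the block, with a median of 0.29 (adjusted p = 1.05e-22, adjusted p = 0.0352 with an estimated correlation).

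Il1b-deficient MmSCs were taken to ask how far Il-1b drives inflammatory transcripts after injury. Il1b (chr2:129364570-129371139) had 0, 0 and 1 counts in the deficient libraries and 2 and 5 in the wild-type libraries, too few to check the labels in these cells. Of the inflammatory genes fixed beforehand, those that passed were higher in deficient MmSCs. Il6 was at 571 ± 13.3 (n = 3) against 362 ± 37.6 CPM (n = 2; 0.66 ± 0.09, adjusted p = 0.0117), and Cxcl5 at 6060 ± 275 against 4540 ± 193 CPM (0.41 ± 0.07, adjusted p = 0.0327). Tnfaip3 (chr10:19000910-19015657) was at 270 ± 26.6 against 109 ± 14.7 CPM (1.31 ± 0.12, adjusted p = 0.00315) and Lif was 0.59 ± 0.12 higher (adjusted p = 0.0459). Ccl2 did not pass (0.25, adjusted p = 0.211). The receptor ligand gene Alkal2 (chr12:30884322-30893854) rose by 3.14 ± 0.35 (adjusted p = 0.00643), Inafm2 by 2.57 ± 0.28, the mesothelial transcription factor gene Wt1 by 2.04 and the serine protease gene Htra1 by 2.03. The immediate-early gene Ier2 rose by 1.86, and Ccdc102a, Arhgap11a, Yipf4, Psmd3 and Lzts2 by between 1.82 and 2.27. Of these, Htra1, Ier2, Ccdc102a, Yipf4, Psmd3 and Lzts2 also lay above the sum in all 3 cytokine interactions. For them a technical source shared with those libraries stays open. The sorbitol dehydrogenase gene Sord fell by 1.56 ± 0.3, the neuropeptide gene Npy by 1.39, Itpa by 1.08 and the transcription factor gene Irf4 by 1 ± 0.19, and Hbegf, Prnp, Htra3 and Gas7 fell by between 0.44 and 0.56. Sord, Itpa and Prnp, like Inafm2 and Arhgap11a, lie within 20 Mb of Il1b. Wt1 (chr2:105126529-105173616) lies on the same chromosome, outside that window. Of 12102 genes 135 rose and 11 fell. Cell cycle genes had 0 called of 30 and 7 higher adjusted over the list alone (median 0.27, adjusted p = 4.06e-05). The cytokine list had 2 of 10 higher, or 4 adjusted over the list alone (adjusted p = 0.0313), and NF-kB targets 2 of 25 higher, or 6 with 2 lower adjusted over the list alone (adjusted p = 0.0249). Interferon response genes had 0 of 27, or 1 lower adjusted over the list alone (median -0.18, adjusted p = 0.0249). All 4 lists had adjusted p = 0.863 with an estimated correlation. The number called was 15, 7 and 13 without deficient replicates 1, 2 and 3, and 670 and 154 without wild-type replicates 1 and 2.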

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

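The tests of explanations in this part were written down before their results were seen, with the following exceptions. The bootstrap interval of the mix minus pairs median was added after that median had been seen, and it turned the verdict on a library batch from ruled out to open. The spread of the label draws, the Gm10800 shares and the fits with Il-17A libraries as the reference were also examined after the results were seen. Each result here was marked because a direct test found that effects differ between groups under the same contrast.

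The injury response of MmSCs differed from the mean of the other compartments in 2398 genes. Cdca7l (6.93), Ncapg (6.43), Steap1 (5.96), Lmcd1 (5.84) and Ube2c (5.7) lay above it in the fitted log2 change, and Ighm (-6.45), Pgf (-6.27), Pla1a (-5.8), Il1r2 (-5.74) and Mlxipl (-5.7) below. Cdca7l, Ncapg, Steap1, Pgf, Pla1a, Il1r2 and Mlxipl have at least 1 group with 0 to 3 counts in all, so their fitted differences depend on the prior count and are no bounds. Of 100 draws of compartment labels within each day, 2 called as many genes, the real labels included, and the highest other draw called 2641. The draws mix cell types inside a group, which raised the biological coefficient of variation from 22.4% to at least 78.5%, and 95 of the 99 other draws called 0 genes, so they do not bear on chance.

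Osm with Il-1b departed from the sum of single effects in 2515 genes. Slc9a3r2 (4.79), Rnf187 (4.57), Prokr1 (4.3), Ccdc102a (4.15) and Gas1 (4.11) lay above the sum, and Csf2rb (-8.71), Ifi208 (-7.57), Csf2rb2 (-7.06), Saa2 (-6.37) and Olfr56 (-6.07) below. With Il-17A libraries in place of PBS, Csf2rb stayed at -8.71 but no longer passed (adjusted p = 0.0711), and Ifi208 (-3.73, adjusted p = 0.0464), Csf2rb2 (-5.52), Rnf187 (2.75) and Gas1 (2.91) passed nearer to the sum. Osm with TNFa departed in 944 genes. Lrrc15 (5.74), Rnf187 (3.65), Irak2 (3.28), Gas1 (3.27) and Zfp703 (3.14) lay above, and Csf2rb2 (-5.89), Saa2 (-5.48), Olfr56 (-4.82), Ifi47 (-4.4) and Has1 (-4.38) below. With Il-17A libraries in place of PBS, Lrrc15 (3.83, adjusted p = 0.348), Rnf187 (1.83, adjusted p = 0.263), Gas1 (2.07, adjusted p = 0.16) and Olfr56 (-4.82, adjusted p = 0.157) no longer passed, and Csf2rb2 (-4.35), Has1 (-2.72) and Zfp703 (2.51) passed nearer to the sum. Osm with Il-17A departed in 409 genes. Rnf187 (4.41), Alkal2 (4.22), Tifa (4.06), Btbd11 (3.71) and Ddit4 (3.42) lay above, and Ccl7 (-3.43), Tmem101 (-2.23), Ccl2 (-2.21), Cldn15 (-2.12) and Bhlhe40 (-1.86) below. Several of these genes have 0 to 3 counts in PBS, and their fitted differences depend on the prior count.

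In the interactions, 146 genes lay above the sum in all 3 pairs (Gm10800, Gm10801, Gm10717 and Gm21738 among them) and 51 below it in all 3, to which the shared PBS and Osm libraries may contribute (not simulated for these contrasts). Gm10800 took 0.869% to 1.64% of counts in PBS and mix libraries and 0.359% to 0.738% in those of single cytokines and pairs, which sets these libraries apart as a library batch would. Such a batch would shift mix against pairs as it shifts PBS against singles (median 1.06 over these genes). The median of mix minus pairs was 0.22 (95% bootstrap interval over genes 0.13 to 0.29). This lay below the 0.53 set beforehand for such a batch, but not clear of the 0.27 under which it was to be ruled out. These genes were chosen by contrasts that add PBS and pairs and subtract singles, which raises the first median and lowers the second. The bootstrap drew genes, so its interval leaves out the spread between libraries. Such a batch and a shared response therefore cannot be told apart. Median GC content (50.8%, against 48.3% to 50.6% in matched random sets) and exon length (2840 bases, against 3123 to 3821) lay outside the range of random sets, so a preparation difference that follows transcript properties may contribute. A common saturation of the response, a biological alternative in this design, was not tested apart from these.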

How the results depend on the processing

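The fits with Il-17A libraries as the reference and the split of the PBS libraries were chosen after seeing the data, and the other alternatives before. Where a cause is not named, the cause was not tested. Numbers called under alternatives stayed within 1.5 times for mix, Il-1b, Osm, Osm pairs and injury in each compartment and mdx at 7 weeks. Without a low-count filter more genes passed for the Il-17A interaction (670), Thy1.1 (360), anti-Cxcl5 (159) and Il1b (594). DESeq2 called 699 for the Il-17A interaction, 120 for Thy1.1, 7 for anti-Cxcl5 and 236 for Il1b. Fits on the compared groups alone gave 1210 for Il-17A and 2027 for mdx at 12.5 against 7 weeks. Leaving out 1 library gave 1182 to 1579 for TNFa, 100 to 334 for Il-17A, 1666 to 2465, 421 to 671 and 109 to 330 for the Il-1b, TNFa and Il-17A interactions, 1571 to 2591 for MmSCs against the other compartments, 0 to 2 for Thy1.1, 0 to 4 for anti-Cxcl5, 137 to 481 for mdx at 12.5 weeks and 7 to 670 for Il1b, each with fewer samples. Of the named genes' values with 1 library left out, 3351 kept direction and side of the threshold, 268 lost the call, 26 gained it and 2 reversed: Saa3 under Osm (-0.3 without Osm replicate 2, up to 5.29 without the other) and Il1b in CD31+ cells (-0.8 without injured replicate 1, up to a fitted 9.57 without uninjured replicate 2).

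With Il-17A libraries in place of PBS, 993 genes were called for TNFa, 1230 for the Il-1b interaction and 214 for the TNFa interaction. In those fits Cxcl1 under Osm was at -0.53, Ccl2 at -2.12 and Nfkbia at -0.18, Ccl2 under Osm with Il-17A was at -2.16, Cxcl1 in the Il-1b interaction at 0.56, and Cxcl1 and Ccl7 in the TNFa interaction at 1.09 and 0.39. Il-17A itself raises Cxcl1 and the Ccl genes against PBS, which this reference subtracts.

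With the replicate block, 1286 genes were called for Thy1.1 and 0 for anti-Cxcl5, and the block moved no other number of calls by over 1.5 times (101 for Il1b). In the other experiments only same-numbered libraries from both groups of a comparison were checked. They correlated at r between -0.193 and 0.122, so no pairing was seen between those groups. Whether same-numbered libraries of different compartments on the same day came from the same muscle was not checked. Of 193 list tests past 0.05, 67 stayed past it with an estimated correlation; fry gave 231 and the block 196. Of 48 signature tests past 0.05, 28 stayed with an estimated correlation, and 45 passed with signatures defined at an adjusted p under 0.01 and a log2 change over 2. The overlap of genes called higher with those higher in the mix, 14012 summed over the 7 comparisons, was 10764 at an adjusted p under 0.01. It was 10266 and 10218 with the mix and the other groups against different PBS libraries. Genes called lower are not in these sums. Depth limits the genes near 0 counts, for which only bounds or intervals are given.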

Other observations

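Of the tests below, those on the repeat family, on strain DNA, on genes shared with the cytokine interactions and on the Thy1.1 pairs were chosen after the results were seen.

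Several list results have not been described. After injury, adipogenic genes fell in 7 of 13 in MmSCs (7 with 1 higher adjusted over the list alone; adjusted p = 0.0404, adjusted p = 0.306 with an estimated correlation), led by Lpl, Pnpla2, Cd36 and G0s2. In Il-17A libraries, oxidative phosphorylation genes rose in 4, or 5 adjusted over the list alone (adjusted p = 7.55e-07, adjusted p = 0.0417 with an estimated correlation). In mdx MmSCs, immediate-early genes fell in 14 and rose in 3 between 2.5 and 7 weeks, or 16 and 3 adjusted over the list alone (adjusted p = 0.00164, adjusted p = 0.374 with an estimated correlation). Between 7 and 12.5 weeks, STAT3 targets rose in 9 and fell in 1, or 12 and 2 adjusted over the list alone (adjusted p = 2.1e-05, adjusted p = 0.271 with an estimated correlation).

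The 4 gene models higher after anti-Cxcl5 vary together. The ratio of each other model to Gm10800 ranged at most 1.9-fold over the 6 libraries while Gm10800 itself ranged 17.9-fold, in line with 1 repeat family counted under several names. Counts of 1408 olfactory receptor genes, which muscle hardly transcribes, summed to between 84.4 and 180 CPM after anti-Cxcl5 and between 40 and 43.4 CPM after IgG, a ratio of 2.88, so carried-over genomic DNA is a candidate source. An effect of the antibody on repeat transcription was not tested apart from this and stays open.

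Of the 146 genes called in Il1b-deficient MmSCs 135 rose, and 6 lie within 20 Mb of Il1b (4.11%, against 1.8% of other tested genes, a ratio of 2.28, Fisher's exact two-sided p = 0.052): Arhgap11a, Inafm2, Itpa, Plcb1, Prnp and Sord. Itpa (-1.08), Prnp (-0.5) and Sord (-1.56) are among the 11 called genes that fell, whereas Arhgap11a, Inafm2 and Plcb1 rose. The test pools both directions, and a test by direction was not run. For the genes in this window, DNA of another strain around the targeted gene may contribute, and the genes are too few to decide. The same holds for 9 more on the same chromosome, Wt1 among them. The remaining 131 lie on other chromosomes, outside any such stretch of DNA (effects of that DNA on genes elsewhere were not tested). Median GC content (50%) lay inside the range of matched random sets (47.7% to 50.6%), so the called genes as a whole showed no shift in GC content. This pooled median cannot exclude a GC effect on part of them, and exon length was not tested for them. Of the called genes 45 are among those that departed from the sum of log2 effects in all 3 cytokine pairs, each in the same direction. Random sets held 3.09 such genes on average, with 7 at the upper end of their central 95%. The named genes Htra1, Ier2, Ccdc102a, Yipf4, Psmd3 and Lzts2 are among the 45. A technical axis shared by both experiments may therefore be a source, and loss of Il-1b itself stays open.

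Comparisons of 3 against 3 libraries allow 10 splits, too few for a share under 0.05. The real split and the highest other called 3855 and 1 genes in CD31+ cells, 5665 and 31 in CD45+ cells, 6852 and 1 in MmSCs, 6357 and 1 in MuSCs, 4 and 0 for anti-Cxcl5, and 5864 and 0 for mdx at 7 weeks. In each of these 6, 1 of the 10 splits, the real one, called that many. Every other split mixes both groups on each side, so real differences widen the spread within a side and lower the calls. The counts therefore do not bear on chance. For Thy1.1 without the block the real and the highest other split both called 0 by edgeR (1258 genes at an unadjusted p under 0.05, 120 by DESeq2 in the real split), so 10 of 10 splits called as many, which cannot set the real split apart. These splits leave out the pairing. With the block, the real split called 1286 and the highest other 0 among the 4 splits that part all 3 pairs, 1 of which, the real one, called as many, and 4 are too few for a share under 0.05. The other splits exchange the labels of 1 pair, which widens the spread in the same way.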
